A study of Mus musculus with 12 samples.

How the data were processed

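RNA was sequenced from 12 libraries of 4T1, a mouse mammary carcinoma cell line, in 4 groups of 3. For the in vivo groups, per the labels' protocols, 5000 4T1 cells carrying the green fluorescent protein mNeonGreen were injected into the tail vein of Balb/c mice, and 100000 4T1 cells per sample were sorted from the lungs 4 weeks later. The groups are called in vivo young and in vivo old after the age label of the mice. For the in vitro groups, cultured 4T1 cells spent 72 h in serum-free medium with 25% interstitial fluid extract (IFE) from the lungs of young or old mice bearing 4T1 metastases. Messenger RNA was selected by its poly-A tail. The protocol names both a strand-specific and an unstranded library type without saying which was used, so antisense and overlapping genes are uncertain here.

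The authors deposited a table of raw counts per gene, a table of normalized values and a table of FPKM for each setting. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2, with no version for the last. The labels hold conflicts. The processing notes name a human genome build, while the rows of the deposited count tables are mouse Ensembl genes. The titles of the in vitro libraries carry the abbreviation shNT, which the protocols do not explain. The series design text describes experiments on a human lung line that are not analysed here. The build behind the gene coordinates is not given in the sources used here. Of 25089 gene identifiers found in the GENCODE M21 annotation of GRCm38, 496 (1.98%) had the same start and end, so coordinates are printed as the files give them and none were taken from that annotation.

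The deposited in vivo count table, as used here, held counts for 5 of the 6 libraries. The deposited normalized signal is the count divided by 1 size factor per library. Multiplying back gave whole numbers for 100.0% of values within 0.001 reads, and these equalled the deposited count for 100.0% of values in the other 11 libraries. The reads of in vivo young replicate 3 were recovered in this way and used with the deposited counts of the others, which departs from the plan to use deposited counts alone. The authors' FPKM values imply a library total of which 9.88% to 10.73% lay outside the table in vivo and -0.56% to 1.38% in vitro. FPKM served only for an alternative test.

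Library totals ran from 11679046 to 15053144 counts in vivo and from 12299004 to 18129164 in vitro. The tables held 24396 genes in vivo and 22035 in vitro, of which 20187 were shared, and they were made separately. Genes with enough counts were kept with edgeR's default filter, which left 14096 genes in vivo and 13118 in vitro. Each setting was fitted on its own 6 libraries with TMM scaling and edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), with group as the single term and robust dispersion estimates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 is what a call means throughout. Standard errors (SE) are the log2 fold change divided by the square root of its F statistic. Levels are CPM, counts scaled for library size in the usual way, as mean and SD of 3 libraries. The difference between the settings was an interaction contrast over all 12 libraries and 14318 genes.

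Before the data were examined, 46 gene lists were fixed, 36 of them programs and 10 of them markers of cell types that a lung sort could hold. A list was tested when 5 or more members passed the filter, with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjustment over the lists of that setting. Each list was also tested with an estimated correlation and with fry. Genes are named by a rule fixed at the same time. It takes the 12 largest rises and 12 largest falls among called protein-coding genes whose groups did not overlap and whose mean was 2 CPM or more, up to 4 called members of lowest p from each changed list, 10 genes named whatever their values, and the 6 genes of lowest p in the interaction. Values of some genes that this rule takes are not reported here. Called genes of each setting were carried to the other as 4 sets with fry (limma), with adjustment over the 4. This test asks whether a set moves on balance in 1 direction and does not compare it with other genes. Fold changes were correlated across genes, with all 20 labelings of the in vitro libraries as the exact permutation test.

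The procedure was tested on simulated counts with 200 changed genes. Among 14096 genes simulated from the in vivo libraries, 46% of 1.25-fold, 68% of 1.5-fold, 86% of 2-fold and 96% of 4-fold changes were recovered, and 8.07% of calls were false. Among 13118 genes simulated from the in vitro libraries these shares were 32%, 72%, 80% and 96%, and 10.3% of calls were false. For the difference between settings, 69% of 2-fold changes among 14318 genes were recovered with 4.17% of calls false. The false shares lie above the nominal level in both single settings.

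The labels do not say that the 3 libraries of a group came from separate mice or separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicates differed by more than sampling noise, with a chi-square per gene of 2.17 to 2.47 in vivo, 2.97 to 3.43 between most in vitro pairs, and 8.18 and 9.43 for the pairs with old IFE replicate 3. No library was merged or left out. Alternatives were DESeq2 1.42.0, other scalings and filters, limma-voom, limma on log2(FPKM + 0.1) over genes with a mean FPKM of 0.5 or more, a fit of all 12 libraries, a test against a fold of 1.2, a score of non-tumour markers as covariate, the replicate number as a block, and each library left out in turn.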

Results

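The data are gene counts from 12 libraries of the mouse mammary carcinoma line 4T1. The in vivo part holds 3 libraries of mNeonGreen-labelled cells sorted from the lungs of young mice and 3 from old mice. The in vitro part holds 3 libraries of cultured cells kept in lung interstitial fluid extract (IFE) of young mice and 3 of cells kept in IFE of old mice. Totals per library were 11679046 to 15053144 counts in vivo and 12299004 to 18129164 in vitro. The series title gives the purpose, which is to use IFE as a model of cancer in old age in vitro. The design implies 3 comparisons, old against young in each setting and the difference between the settings.

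The first comparison asked how 4T1 cells from old lungs differed from those of young lungs. Genes of class II antigen presentation were lower in the old libraries. Cd74 (ENSMUSG00000024610, chromosome 18, 60936920 to 60945724 in the file's coordinates, build not given), the invariant chain of class II molecules, fell from 1364 ± 9.44 to 226.1 ± 6.54 CPM (SD, n = 3 each). The tight junction gene Cldn4 rose 2.168-fold, from 241 ± 5.53 to 522.6 ± 9.43 CPM. In all, 5639 of 14096 genes were called by edgeR's quasi-likelihood test, 2758 higher and 2881 lower in old. A change of 2-fold or more was seen for 187 of the higher and 782 of the lower genes. All 3 old libraries lay above or below all 3 young ones for 47.7% of genes tested, against 10% by chance.

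Markers of non-tumour cells moved with the groups in these sorted libraries. Of 21 macrophage and monocyte markers tested, 19 fell, 1 rose and 1 did not pass. The median log2 fold change was -3.05. C1qa, a subunit of complement C1q made by macrophages, fell from 149.7 ± 0.525 to 15.89 ± 1.8 CPM. Mrc1, the mannose receptor, fell from 128 ± 1.95 to 15.53 ± 1.91 CPM. The summed markers made up 0.156% of counts in young and 0.0238% in old libraries. All 7 class II genes tested fell, with a median of -2.71, among them H2-Ab1, which was 8.173 times as high in young as in old. Markers of alveolar and airway epithelium went the other way, with 8 of 14 higher and 2 lower. Sftpc, a surfactant protein of alveolar type II cells, rose from 13.04 ± 0.292 to 42.23 ± 2.18 CPM. That list was called by camera with the preset correlation (adjusted p = 0.00031) and by fry (adjusted p = 0.00033). With an estimated correlation it was not called (adjusted p = 0.0967, camera).

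**Figure D1:**
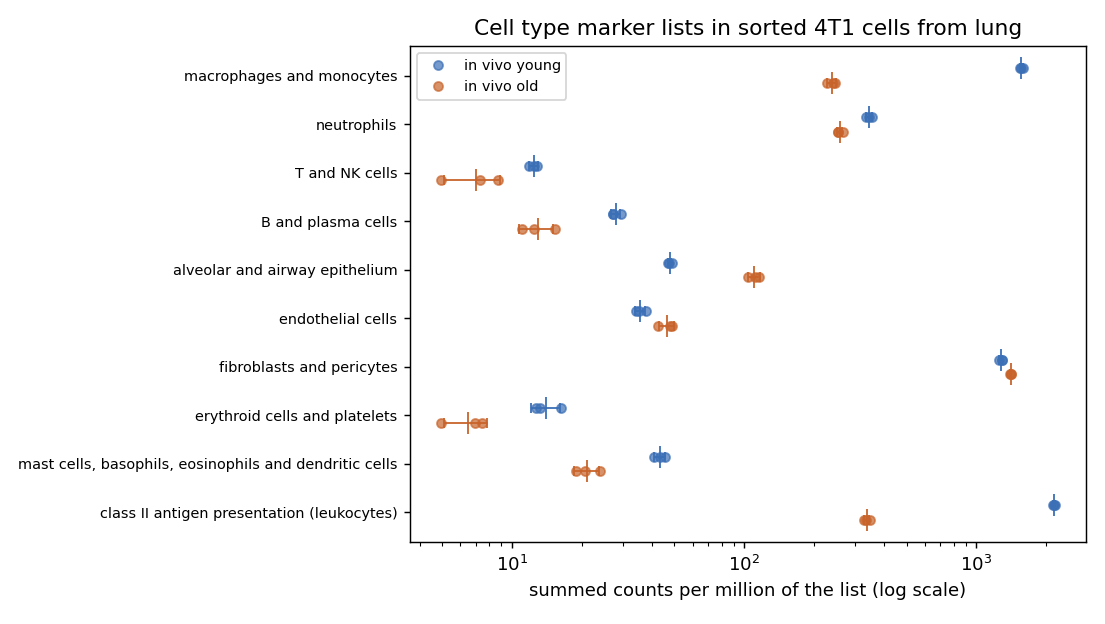
Summed CPM of 10 cell type marker lists (log scale) in each in vivo library, with points for libraries and bars for mean ± SD of 3. Macrophage markers summed to 1562 in young and 238.1 in old libraries, while alveolar and airway markers summed to 47.72 and 110.2.

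Of the 12 largest falls, 1 gene, Fcgr1, was on the macrophage list, which holds only 24 genes. Absence from that list does not show that a gene's RNA came from 4T1 cells. Ccl8 and Ccl12, chemokines that attract monocytes, were 32.34 and 27.6 times as high in young as in old libraries. With 1 library left out, their log2 fold changes ran from -5.327 to -4.784 and from -6.038 to -4.261. Fcgr1, a high-affinity Fc receptor of macrophages, fell from 25.92 ± 1.69 to 1.404 ± 0.374 CPM. Il21r, Htr7, Clec4a1, Mgl2, Pdcd1lg2, Clec4a3, Ms4a6b, Pf4 and Tm6sf1 completed the 12 largest falls. Their log2 fold changes ran from -5.67 for Il21r to -4.19 for Tm6sf1. That of Il21r lay between -6.818 and -5.147 with 1 library left out. Among the 12 largest rises, Eln, which encodes elastin, rose from 5.386 ± 0.794 to 25.6 ± 2.12 CPM. The metalloprotease gene Adam12 rose 4.533-fold, to 27.74 ± 1.15 CPM. The others were Lyz1, Mab21l4, Cxcl15, Igf2bp1, Sftpa1, Igfbp3, Sele, Cobl, Tent5b and Cgref1. Lyz1 rose from a low level, 0.7149 ± 0.132 CPM in young, to 4.083 ± 0.136 CPM in old libraries. Lyz1 and Sftpa1 are on the alveolar and airway list, and Lyz1 is also on the macrophage list.

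Interferon and antigen presentation genes fell together in the old libraries. All 30 type I interferon response genes fell (median log2 fold change -0.74), as did all 25 genes of antigen presentation and interferon gamma response (median -0.90). Bst2, an interferon-induced membrane protein, fell from 165 ± 4.62 to 88.67 ± 2.57 CPM, and Tap1, a peptide transporter for class I loading, fell from 268.9 ± 3.47 to 122.4 ± 2.12 CPM. B2m, the class I light chain, fell from 1621 ± 2.08 to 1118 ± 27.2 CPM. Of 29 inflammatory cytokine and NF-kB genes, 21 fell and 4 rose (23 and 4 adjusted over the list alone). Il1b fell from 168.5 ± 2.61 to 26.91 ± 2.21 CPM. Complement and coagulation genes fell in 11 of 16 cases, with C3 at 335 ± 6.42 in young and 172.3 ± 0.664 CPM in old. Lysosome and autophagy genes fell in 19 of 28 cases, with the protease gene Ctsb going from 1035 ± 14.9 to 636.7 ± 11.1 CPM. The macrophage markers fell in the same libraries. These 5 lists, the macrophage list and the class II list were also called with an estimated correlation.

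Chaperones of the endoplasmic reticulum were lower in old libraries. Of 20 genes tested, 19 fell, including Calr (840.2 ± 23.1 to 559.2 ± 17.3 CPM) and Hsp90b1 (933.6 ± 5.8 to 653.4 ± 14.4 CPM). This list was near the threshold with an estimated correlation (adjusted p = 0.04998). B and plasma cell markers fell in 4 of 5 cases, Igkc among them. That list lost its call with an estimated correlation (adjusted p = 0.239), with no filter on low counts (adjusted p = 0.11) and without each of 4 libraries, young replicates 1 and 2 and old replicates 1 and 3 (adjusted p 0.056 to 0.091).

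Epithelial genes were higher in the old libraries. Of 23 epithelial identity genes tested, 18 rose and 1 fell. Epcam, an epithelial adhesion molecule, rose from 154 ± 6.02 to 262.9 ± 7.24 CPM, and the keratin gene Krt7 rose from 224 ± 1.81 to 376.4 ± 4.83 CPM. Collagens and matrix proteins rose in 21 of 29 cases and fell in 5 (6 adjusted over the list alone). Lamb3 rose from 63.97 ± 1.56 to 164.1 ± 8.58 CPM, whereas Col6a1 fell from 705.6 ± 11.1 to 541.8 ± 9.84 CPM. YAP/TAZ targets rose in 14 of 19 cases and fell in 2 (3 adjusted over the list alone), with Ccn2 (ENSMUSG00000019997), a matricellular growth factor, going from 25.98 ± 1.31 to 80.6 ± 7.4 CPM. Cholesterol biosynthesis genes rose in 17 of 24 cases (18 adjusted over the list alone) and fell in 1, with Hmgcs1 going from 83.33 ± 1.42 to 122.3 ± 9.54 CPM. These 4 lists were also called with an estimated correlation, but the cholesterol list lost its call with a score of non-tumour markers as covariate (adjusted p = 0.13). In the same libraries 8 of 14 alveolar and airway markers and 8 of 13 fibroblast markers were higher (adjusted p = 0.0967 and 0.252 with an estimated correlation). The fibroblast markers that rose include Col1a1, Col1a2 and Col3a1, which are also on the collagen list.

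The 6 other lists called higher in vivo lost the call with an estimated correlation. Apart from the alveolar list above, they were the cytosolic ribosomal proteins, with 39 of 44 higher (adjusted p = 0.292 with an estimated correlation), TGF-beta targets, with 12 higher and 4 lower of 24 (adjusted p = 0.121), ATF4 and integrated stress genes, with 12 higher and 3 lower of 27 (adjusted p = 0.143), adhesion and metastasis genes, with 10 higher and 3 lower of 24 (adjusted p = 0.225), and fibroblasts and pericytes, with 8 higher and 2 lower of 13 (adjusted p = 0.252). Adjusted over the list alone, TGF-beta targets had 13 higher and 5 lower, adhesion genes 10 and 4, and fibroblast genes 9 and 2. In the in vivo lists not given such a count, it equalled the count over all genes for each list named here. The fibroblast list also lost its call without young replicate 1 (adjusted p = 0.057). The ribosomal changes were small. Rpl5 was 1.214 times as high in old, and counts of such genes are uncertain because near-identical copies share reads. Tgfbi, a member of the TGF-beta list, fell from 157.6 ± 1.81 to 31.68 ± 0.61 CPM.

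Targets of the glucocorticoid receptor did not move as a group. Of 23 tested, 8 were higher and 8 lower (8 and 10 adjusted over the list alone; adjusted p = 0.774, camera). Fkbp5 rose from 186.1 ± 3.94 to 231.1 ± 0.89 CPM and Tsc22d3 from 59.68 ± 1.26 to 72.41 ± 5.72 CPM, while Per1 fell from 269.6 ± 6.61 to 233 ± 4.39 CPM and Sgk1 from 936.4 ± 8.87 to 797.2 ± 8.98 CPM. The receptor gene Nr3c1 stood at 81.15 ± 3.11 CPM in young and 77.97 ± 5.06 in old (adjusted p = 0.356, edgeR). Sox4 rose 1.293-fold and Cdkn1a fell to 0.8209 of its young level. The proliferation marker Mki67 stood at 329.7 ± 5.98 and 338.7 ± 4.32 CPM (adjusted p = 0.279, edgeR). Zbtb16 and Cdkn2a had too few counts to be tested.

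The in vivo count fell to 1853 genes when tested against a fold of 1.2. With a score of non-tumour markers as covariate it was 155, and the median standard error of the 5639 genes was 0.549 against 0.0702 on the log2 scale. It was 4906 without young replicate 3, which leaves deposited counts alone, and 4608 among genes at 2 CPM or more in culture, an alternative chosen after seeing the data. With the preset correlation, camera also called 10 to 17 lists in the other 9 splits of these 6 libraries, against 19 in the real one. With an estimated correlation it called 12 lists in the real split and 0 in each of the others. Every other split mixes old with young libraries, so a real difference enters the spread and the estimated correlation there. Neither count thus shows how many lists would be called without any difference.

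The second comparison asked how cultured 4T1 cells differed between IFE of old and of young mice. Differences were few and small. Ccn2 was 1.519-fold higher with old IFE, at 63.01 ± 7.28 against 41.45 ± 2.83 CPM, and Actg1 (ENSMUSG00000062825), which encodes gamma-actin, was 1.3-fold higher, at 672.2 ± 10.7 against 517.1 ± 18 CPM. Txnip, a thioredoxin inhibitor that responds to glucose, fell to 0.7642 of its level, from 120.8 ± 4.72 to 92.37 ± 8.82 CPM. Of 13118 genes, 11 were called, 7 higher and 4 lower with old IFE, and 929 had an unadjusted p under 0.05. The other rises were Cnn2 (1.354-fold), Wnt7a (1.348-fold), Bhlhe40 (1.293-fold), Msln (1.267-fold) and Ltbp2 (1.265-fold). The other falls were Il23a, Tfrc, the transferrin receptor, and Btg1, with log2 fold changes of -0.29, -0.27 and -0.23.

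**Figure D2:**
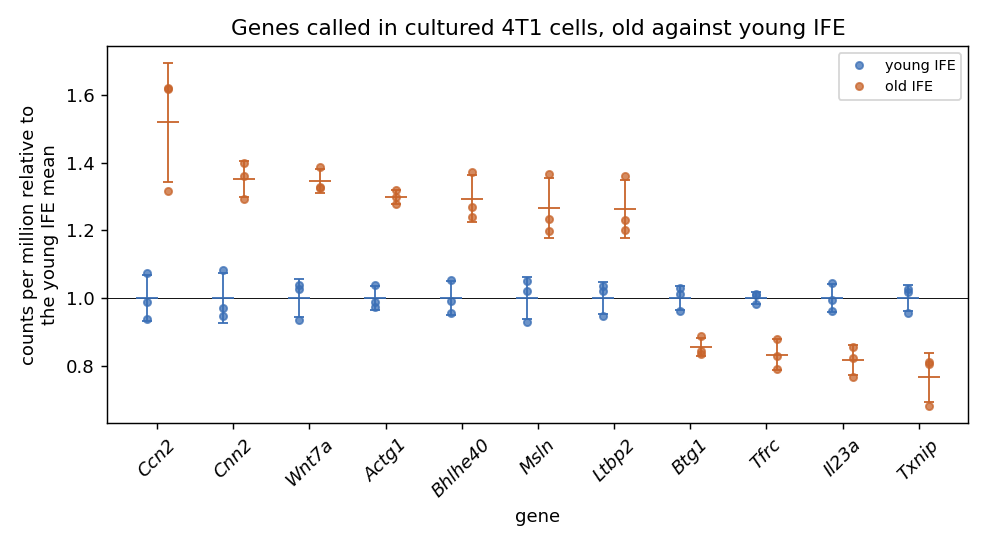
CPM relative to the young IFE mean for the 11 genes called in vitro, with points for libraries and bars for mean ± SD of 3 libraries. Ccn2 has the highest ratio (1.519-fold in the fit) and Txnip the lowest.

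The count depended on single libraries and on the tool. It was 183 without old IFE replicate 3, the library that stood apart from its group, and 8 without old IFE replicate 1. It was 1 without old IFE replicate 2, 1 without young IFE replicate 1, 2 without young IFE replicate 2 and 1 without young IFE replicate 3. DESeq2 called 30 genes and limma-voom 1. Actg1 was called with each library left out, with adjusted p up to 0.0215 (edgeR), but not with limma on log2(FPKM + 0.1) (adjusted p = 0.0557) or against a fold of 1.2. The 1 gene called with limma on FPKM was none of the 11.

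Of 37 lists tested in vitro, 6 were called with the preset correlation and 0 with an estimated one. YAP/TAZ targets had a positive fold change in 14 of 19 cases with 1 gene called, Ccn2 (adjusted p = 4.2e-05, and 0.571 with an estimated correlation). TGF-beta targets had one in 16 of 23 cases with 3 called, Ccn2, Bhlhe40 and Ltbp2 (adjusted p = 7.43e-05, and 0.236 with an estimated correlation). Adjusted over the list alone, 6 TGF-beta targets were higher and 2 lower, and 2 YAP/TAZ targets were higher. Collagens and matrix proteins had 14 of 19 positive and 0 called (adjusted p = 0.236 with an estimated correlation). Antigen presentation and interferon gamma genes had 19 of 21 positive and 0 called (adjusted p = 0.814 with an estimated correlation), and without old IFE replicate 3 the direction turned (adjusted p = 0.85). ATF4 and integrated stress genes had 5 of 27 positive and fatty acid oxidation genes 6 of 15, with 0 called and, adjusted over the list alone, 3 and 2 lower (adjusted p = 0.627 with an estimated correlation for both). Without old IFE replicate 3 these 2 lists had adjusted p of 0.12 and 0.19. With the preset correlation, the YAP/TAZ, TGF-beta and collagen lists kept their calls with each library left out (adjusted p up to 0.0022, 0.0016 and 0.018, camera). Other splits of the 6 libraries gave 3 to 11 lists, and 6 of the 9 gave at least as many as the real one. The number of lists called in vitro thus does not stand apart from other splits, although these mix old with young IFE.

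Glucocorticoid receptor targets had a positive fold change in 6 of 21 cases with 0 called (adjusted p = 0.0573, and 0.799 with an estimated correlation). Adjusted over the list alone, 1 was lower. The list was called lower without young IFE replicate 3 (adjusted p = 0.037) and without old IFE replicate 1 (adjusted p = 0.0067), in a range of 0.0067 to 0.24 over the libraries left out. Fkbp5 stood at 71.05 ± 2.69 CPM with young and 69.35 ± 3.52 with old IFE, Nr3c1 at 189.5 ± 2.28 and 188.6 ± 3.79, and Mki67 at 128.6 ± 8.3 and 132.2 ± 6.23. Macrophage markers summed to 9.671 ± 1.54 and 10.69 ± 1.4 CPM in culture.

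The third comparison asked whether the change between old and young differed between the settings. Cd74 fell in vivo and stood at 42.17 ± 3.7 and 50.43 ± 4.41 CPM in vitro, a difference of -2.86 between the log2 fold changes (adjusted p = 6.64e-21, edgeR interaction). Ctsc, Lcp1 and Lgmn, genes of lysosomal proteases and of a leukocyte actin-bundling protein, also had more negative changes in vivo (-2.57, -2.04 and -1.36). Macrophage markers summed to 1562 (young) and 238.1 CPM (old) in vivo, but to 9.671 and 10.69 in culture. The contrast therefore cannot tell a change in macrophage RNA in vivo from a change in 4T1 cells. Cldn4 had a more positive change in vivo (1.02). In all, 2501 of 14318 genes differed, 1303 more positive and 1198 more negative in vivo. Ccn2 rose in both settings and by more in vivo (difference 1.03). Wnt7a (difference 1.24) and Msln (0.28) also rose in both. Actg1 rose in both and by less in vivo (-0.20).

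**Figure D3:**
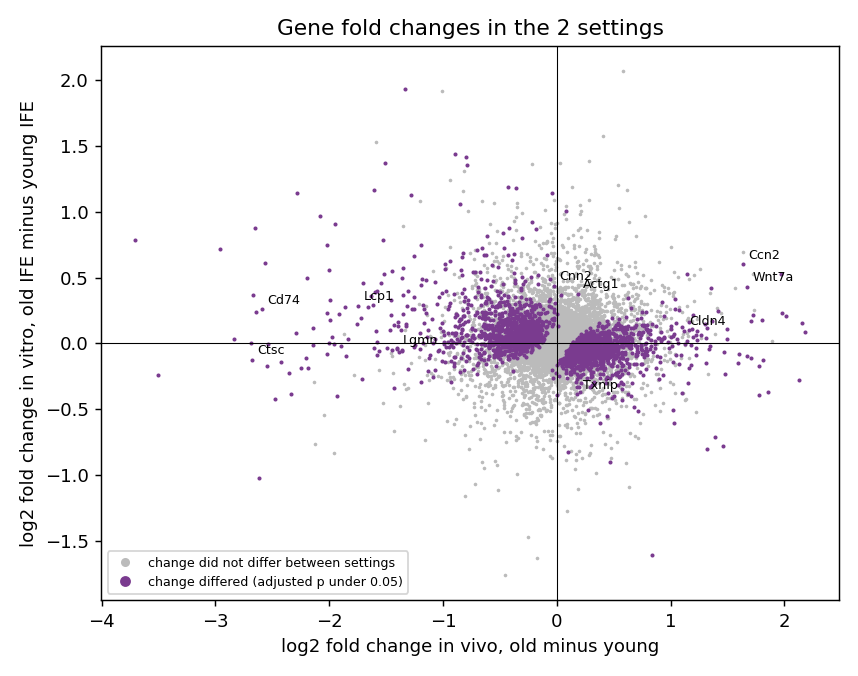
Log2 fold change of each gene in vivo (old minus young, horizontal) against in vitro (old IFE minus young IFE, vertical), with colour for genes whose change differed between the settings. Cd74 and Ctsc lie far left, at 0.26 and -0.12 on the vertical axis, while Ccn2 and Wnt7a lie to the upper right.

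Across the 12477 genes tested in both settings, the fold changes had a Pearson r of -0.064 and a Spearman rho of -0.048 across genes, which are not independent replicates. The exact permutation p over 20 labelings of the in vitro libraries was 0.8 (one-sided, smallest possible 0.05). Genes that rose in vivo had a positive fold change in vitro in 50.7% of 2635 cases (adjusted p = 0.79, fry), and genes that fell in vivo had a negative one in 42.7% of 2175 cases (adjusted p = 0.17, fry). With only the 100 genes of lowest p that rose in vivo, fry passed 0.05 toward higher in vitro, by an unadjusted p. Of all genes tested, 51.9% had a positive fold change in vitro and 50.3% in vivo. In the reverse direction, 5 of the 7 genes higher in vitro had the same sign in vivo and 4 were called (adjusted p = 9.2e-06, fry), these being Ccn2, Wnt7a, Actg1 and Msln, while Ltbp2 was lower in vivo. The call was lost with the 100 genes of lowest p in that direction. Only 4 genes were lower in vitro, so the 100 of lowest p were used in their place, and 42 of 98 had the same sign in vivo (adjusted p = 0.004, fry, toward higher). With the genes that DESeq2 called lower in vitro, the direction in vivo turned.

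**Figure D4:**
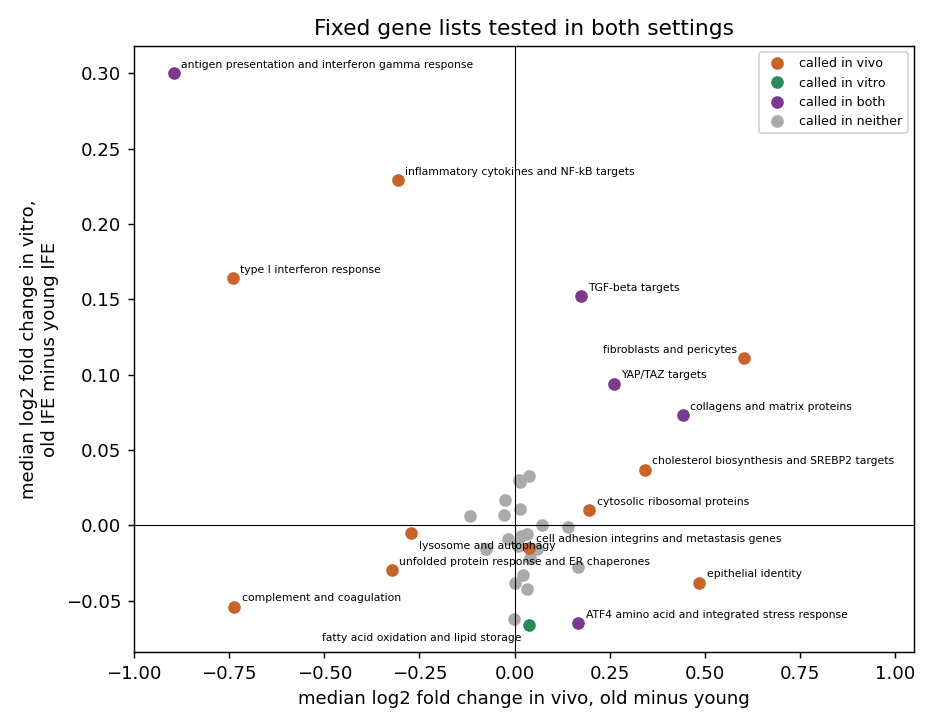
Median log2 fold change of each gene list tested in both settings, in vivo (horizontal) against in vitro (vertical), coloured by the setting in which camera with a preset correlation called it. Antigen presentation genes lie at -0.90 in vivo and 0.30 in vitro, and YAP/TAZ targets at 0.26 and 0.09.

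Among lists measured in both settings, those whose change differed under both correlation settings were epithelial identity, more positive in vivo (median difference 0.50, adjusted p = 0.000729 with an estimated correlation), and 2 that were more negative in vivo. These were lysosome and autophagy (-0.28, adjusted p = 0.00178) and endoplasmic reticulum chaperones (-0.32, adjusted p = 0.035). The difference of the macrophage list is not given, since 2 of its genes passed the filter on low counts in vitro, too few to measure a change there. For the interferon gamma list the adjusted p was 0.222 with an estimated correlation.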

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

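All explanations of cell content, pooling and single libraries below were tested after the results were seen, while the counts over other splits of the libraries were planned before. The change between old and young differed between the settings for 2501 genes by an interaction test. The differences of log2 fold changes, in vivo minus in vitro, were -2.86 for Cd74, -2.57 for Ctsc, -2.04 for Lcp1, -1.36 for Lgmn and 1.02 for Cldn4. Among glucocorticoid-related and other genes named whatever their values, they were 0.34 for Fkbp5, 0.42 for Tsc22d3, -0.39 for Per1, -0.33 for Sgk1 and 0.31 for Sox4. A change in macrophage RNA in vivo would also enter such differences, since macrophage markers were scarce in culture. Antigen presentation and interferon gamma genes differed by a median of -1.16 and ATF4 and integrated stress genes by 0.14, both with opposite directions in the settings. Without old IFE replicate 3 the in vitro direction of the first list turned (adjusted p = 0.85) and the second lost its in vitro call (adjusted p = 0.12). These list calls were lost with an estimated correlation (adjusted p = 0.222 and 0.26). The other lists called in both settings with the preset correlation were YAP/TAZ targets, TGF-beta targets, and collagens and matrix proteins. They were higher with old in both settings, but their in vitro calls were lost with an estimated correlation.

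Of 100 drawn splits of the 12 libraries within the settings, 1 gave as many interaction genes as the real split, namely the real split itself, and the highest other gave 2404. The 11 other splits that kept the real in vivo groups gave 1836 to 2404 genes, and the splits that broke them up gave at most 1. Most of the interaction count thus follows the in vivo groups and comes back when the in vitro labels are exchanged. The in vivo libraries make 10 splits, too few for a share under 0.05, so these counts exclude a random grouping of neither the in vivo nor the in vitro libraries taken alone.

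For the other counts the 6 libraries of a setting make 10 splits, too few for a share under 0.05. Every split but the real one also mixes old with young libraries, so a real difference widens the spread there. The real in vivo split gave 5639 genes and the highest other 0, with 1 of 10 splits as large. The real in vitro split gave 11 genes and the highest other 0, again 1 of 10. In vivo lists numbered 19 in the real split and at most 17 in the others, 1 of 10. In vitro lists numbered 6 in the real split and up to 11 in the others, with 7 of 10 splits as large. For the in vivo genes carried to the in vitro libraries, 2 of 10 splits gave a fry p as small as the real 0.13, the lowest other being 0.06.

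Macrophage and class II genes were lower in the old in vivo libraries, although the mNeonGreen sort should have removed cells without the label. Alveolar and airway markers had a median of 1.155, higher in old, so the non-tumour markers did not all fall together. That cannot decide whether the overall share of 4T1 cells was lower in young, since each cell type can vary on its own. Alveolar and airway markers summed to 47.72 CPM in young and 110.2 in old, and macrophage markers to 1562 and 238.1. A larger share of macrophage RNA in the young libraries may account for the pattern. Of 19 macrophage markers under 2 CPM in culture, 15 (78.9%) lay within 1 log2 unit of their median of -3.15, against a bound of 75% set after the quartiles were known, and the most abundant, Lyz2, fell from 409.8 to 72.36 CPM. Of the 21 markers, 2 stood at 2 CPM or more in culture, and Lyz1, which rose, is also on the alveolar list. An age difference in the number of macrophages, or in what they take up, stays open and untested.

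In vivo replicates agreed closely, with a common biological coefficient of variation of 3.87%. Summed macrophage markers varied by at most 4.25% within a group, which is consistent with replicates drawn from 1 cell pool per group. Mice that happened to be alike would give the same value, so separate animals are not excluded, and the labels do not say.

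Antigen presentation and interferon gamma genes were called higher with old IFE in vitro. Without old IFE replicate 3 the adjusted p was 0.85 and the direction turned, while the call held without each of the other 5 libraries. A candidate explanation is therefore that this library alone carries the pattern. Why it differed from its group was not tested, and a difference between IFE preparations stays open.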

How the results depend on the processing

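The alternatives limited to genes at 2 or 10 CPM in culture were chosen after seeing the data, the others before. The in vivo count of 5639 stayed within 1.5 times under all alternatives except a test against a fold of 1.2 (1853 genes, where a smaller set is built into the test) and the non-tumour score as covariate (155, of which 142 were among the 5639), a score that separates the in vivo groups. Of the 5497 genes that lost their call with it, 74.4% kept their sign, with a median absolute log2 fold change of 0.475 against 0.315 and a median standard error of 0.553 against 0.0703. Epcam, for example, went from 0.77 (SE 0.034) to 0.84 (SE 0.283, adjusted p = 0.184), so its call ended by the wider error, while Cobl went from 1.81 (SE 0.31) to 0.07 (SE 3.087). Leaving out 1 library gave 4906 to 5252 in vivo genes. The in vitro count of 11 became 30 with DESeq2, 70 with no filter, 65 with all 12 libraries in one fit, 29 with the score as covariate, 1 with limma-voom, 1 with limma on FPKM and 0 against a fold of 1.2 (116 genes had an unadjusted p under 0.05 there). Without 1 library it ranged from 1 to 183. The cause of these shifts was not tested. All 11 genes were among those called by DESeq2 and without old IFE replicate 3.

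Same-numbered libraries had deviations correlated by -0.027 to 0.031 over all genes, and other pairs by -0.05 to 0.037. The replicate numbers thus gave no sign of pairing. A pairing that affects few genes is not excluded, and the labels do not say. With the replicate block the counts were 5655 in vivo, 7 in vitro and 2458 for the interaction, with 19 and 6 lists. The interaction count was within 1.5 times of 2501 under all alternatives, and 1946 to 2985 with 1 library left out.

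In vivo lists numbered 12 with an estimated correlation, 35 with fry, which does not compare a list with other genes, and 15 with the score as covariate (14 of them shared), against 19. Limited to genes at 2 CPM or more in culture, camera called 13 lists. Of the 19 lists, 13 could be tested there and 12 kept the call. With the score the calls of cholesterol (adjusted p = 0.13), ATF4 (0.13), TGF-beta (0.41), adhesion (0.6) and B and plasma cell genes (0.41) were lost, and nuclear oxidative phosphorylation was called higher (0.0083). Leaving out 1 library gave 17 to 19. In vitro lists numbered 0 with an estimated correlation (3 at an unadjusted p under 0.05), 0 with fry (2 at an unadjusted p under 0.05) and 11 with the score as covariate, and 6 to 12 with 1 library left out. Without old IFE replicate 3, the antigen presentation list turned (adjusted p = 0.85), as did inflammatory cytokines (adjusted p = 0.00018). Over all 6 libraries left out, their adjusted p ran from 1.1e-09 to 0.85 and from 0.00018 to 0.66. Ighm turned in vivo with the score as covariate (log2 fold change 1.36, adjusted p = 0.844). For carried genes, calls under the alternatives rest on fry's unadjusted p under 0.05. The 100 of lowest p gave medians of 0.0369 (from in vitro higher, call lost) and 0.0603 (from in vivo higher, call gained). The DESeq2 list of in vitro lower genes gave -0.0219, a reversal. The cause was not tested. The correlation of fold changes moved by less than its jackknife error of 0.067 in every alternative run (-0.099 to -0.004 with 1 library left out). Of the values for named genes and single lists, 2926 kept their side of the threshold, 196 lost a call and 40 gained one. Those of the 2926 that were called also kept direction, while direction was not compared for values without a call. In the simulated counts, where few genes were changed, many changes under 1.5-fold were missed at these depths. The adjusted p depends on how many genes change, and the real data had far more calls in vivo and far fewer in vitro. The simulated shares therefore do not measure how many small changes were missed in either setting.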

Other observations

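Cell cycle lists were not called by camera in either setting. In vivo, 7 of 30 mitosis genes were higher and 4 lower (adjusted p = 0.537, camera), and 7 of 30 replication genes were higher and 4 lower (adjusted p = 0.293). Hypoxia genes went both ways, with 6 higher and 10 lower of 25, or 8 and 10 adjusted over the list alone (adjusted p = 0.545). Propionate and methylmalonate genes had 3 higher and 2 lower of 16 (adjusted p = 0.537). In vitro, 0 genes of the mitosis, replication and propionate lists were called by edgeR, and 1 hypoxia gene, Bhlhe40, was higher, or 1 higher and 3 lower adjusted over the list alone. Neutrophil markers summed to 344 ± 10.3 CPM in young and 257.4 ± 7.43 in old in vivo libraries (SD, n = 3), with 4 of 13 lower (adjusted p = 0.358). Endothelial markers had 7 of 15 higher and 1 lower (adjusted p = 0.197). By fry, which does not compare a list with other genes, 4 of these lists were called in vivo. Replication genes (adjusted p = 0.0056) and endothelial markers (0.0085) were higher, and hypoxia genes (0.0061) and neutrophil markers (0.0041) lower.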
